A study of Mus musculus with 10 samples.

How the data were processed

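RNA-seq was run on 10 libraries of mouse prostate cancer organoids: 3 given DMSO and 3 given 1 µM DZNep in the chemical experiment, 2 given EtOH and 2 given 1 µM Tamoxifen in the genetic one, collected at 3 days. Per the labels' protocols, total RNA was extracted with TRIzol and stranded mRNA libraries were made with the Illumina TruSeq kit from 500 ng. Per the submitters' processing notes, bcl2fastq 2.18, STAR and Cufflinks were used with genome build mm9, and versions of STAR and Cufflinks were not given in the sources used here. The authors deposited 2 tables of log2 RPKM values, 1 per experiment, with a floor of 0, which fits log2(RPKM + 1). How strand and multiply aligned reads were treated, and whether the tables were normalized together, is not given in the sources used here. RPKM was recovered as 2 to the power of the value less 1. Each table held 24043 gene rows. The table of the genetic experiment also held 2 rows without values, which are not in that number. Of its 24043 rows, 27 had symbols turned into dates and were left out, leaving 24016. Matching to the reference gene table succeeded for 23818 and 23791 symbols. That table describes another build than mm9, so it served for names and gene types only and no coordinates are given.

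Counts cannot be recovered from these values, so no count model was used. Genes with a mean of at least 1 RPKM over the libraries of a table were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a mean trend, two-sided), each experiment alone, with 4 and 2 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. The difference between experiments was tested in 1 limma fit of 4 group means over all 10 libraries. Its terms are differences within a table, so levels were never tested across tables. EZH2 also had an exact permutation test.

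Gene lists, 25 in number, were tested with camera at a preset inter-gene correlation of 0.01 where at least 3 members passed the filter, adjusted over the lists of an experiment, and again with an estimated correlation and with fry (statmod 1.5.0). They were interferon-stimulated genes, MHC class I and class II presentation, sensing of double-stranded RNA and cytosolic DNA, checkpoint ligands and T cell chemokines, NF-kB and TNF response, the PRC2 complex, canonical PRC2 targets, germline genes, the methionine cycle, S phase, G2 and M phase, MYC targets and ribosome biogenesis, androgen receptor targets, luminal, basal, neuroendocrine, fibroblast and smooth muscle, immune and endothelial markers, p53 targets, ATF4 and unfolded protein response, cholesterol biosynthesis, epithelial-mesenchymal transition, and immediate early and heat shock genes. After the data were seen, 4 lists were added: squamous, mucosal secretory and urothelial genes, and interferon ligands and receptors.

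The named genes followed a rule. In each experiment these were EZH2, the 5 largest rises and 5 largest falls past the threshold with treated and control libraries fully separated, the 4 interferon-list members of smallest p, 2 each from MHC class I, sensing, checkpoint ligands, PRC2 complex and PRC2 targets, and 2 of each other list that passed camera. For the difference they were the 4 genes of smallest p and up to 4 called in both with the largest product of changes of 1 sign. A gene named in 1 experiment may be given for the other, and a list of up to 10 measured members in full. Other list members are named where few passed, after their values were seen, and 1 of these is not reported here. The groups, tests, 25 lists, this rule and all alternatives but 1 were fixed before the data were examined. Fisher's exact test of the overlaps was not among the planned tests, nor were the camera and fry tests of genes changed at least 2-fold with DZNep.

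Alternatives were a pseudocount of 0.1, no filter, a filter of 5 RPKM, quantile normalization, trimmed mean scaling, no trend, robust variances, a replicate block, 1 joint fit of all 10 libraries, and leaving out each library in turn. Leaving out short RNA genes was added later. The procedure was tested on simulated data. For DZNep (11143 genes) 85.1%, 98.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, for Tamoxifen (11123 genes) 52.2%, 95.5% and 98.5%, and for the difference (10994 genes) 67.2%, 94.0% and 100%. False calls were 3 of 192 and 4 of 168, and 0 genes were called in data with no change. The simulation drew each gene independently, with no variation shared by the genes of a library. Within an experiment it placed changes only in the more strongly expressed genes. These rates may therefore not carry over to the deposited data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.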

Results

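RNA was sequenced from mouse prostate cancer organoids, 3-dimensional cultures grown from the dorsal-lateral lobe of C57BL/6 mice at 8 weeks of age. The mice carried a MYC overexpression construct, floxed Ezh2 alleles and CreERT2, a recombinase that Tamoxifen activates, under a PSA promoter. All cultures were kept in 10 nM R1881, a synthetic androgen. The purpose stated for the series was to compare control organoids with organoids in which EZH2, the histone methyltransferase of Polycomb repressive complex 2 (PRC2), was inhibited chemically or genetically. In the chemical experiment, 3 libraries from 1 µM DZNep were set against 3 from DMSO. DZNep blocks S-adenosylhomocysteine hydrolase and was used in the series as an EZH2 inhibitor. In the genetic experiment, 2 libraries from 1 µM Tamoxifen were set against 2 from ethanol (EtOH). RNA was taken after 3 days. Nothing in the labels says that replicates were separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

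The deposited values were log2(RPKM + 1) per gene, and the symbols are given in capitals as deposited. Each library listed between 15021 (EtOH 1) and 15404 (DZNep 1) genes above 0 and between 11037 and 11094 genes at 1 RPKM or more. RPKM totals ran from 469455 (DMSO 3) to 512726 (DMSO 1), and the 10 most abundant genes held 7.18% to 8.81% of a library's total. Absolute depth is not known from RPKM. The spacing of the lowest values put relative depth between 0.753 (DZNep 2) and 1.16 (DMSO 3), with DMSO 1 set to 1, from the most common ratio of 692 to 848 weakly expressed genes per library. That ratio held for only 24.4% to 30.7% of them. The first principal component carried 71.0% of the variance of the chemical experiment and separated DZNep from DMSO. In the genetic experiment it carried 70.1%, with scores of -15.999 for EtOH 1, -5.80 for EtOH 2, 9.27 for Tamoxifen 1 and 12.5 for Tamoxifen 2.

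The first comparison asked how 3 days of DZNep altered expression. Interferon-stimulated genes rose together. Of the 52 tested members of that list, 50 rose and 0 fell, and all 52 rose when p-values were adjusted over the list alone. RTP4, an interferon-inducible chaperone of G protein-coupled receptors, went from 1.30 ± 0.446 to 17.5 ± 0.715 RPKM (mean ± SD, n = 3 each), a log2 change of 3.03 (SE 0.133; adjusted p = 7.53e-06). ISG15, a ubiquitin-like protein conjugated to targets after interferon, went from 2.16 ± 0.0916 to 21.9 ± 0.909 RPKM (log2 change 2.86, SE 0.0517; adjusted p = 1.87e-07). IFIT1, which binds foreign RNA, rose by 2.77 (SE 0.0821; adjusted p = 1.52e-06), from 1.12 ± 0.235 to 13.4 ± 0.248 RPKM. CXCL10, a chemokine that attracts T cells, rose by 2.62 (adjusted p = 4.06e-06), from 2.11 ± 0.369 to 18.2 ± 1.71 RPKM. OASL2, of the oligoadenylate synthetase family, rose by 2.27 and XAF1, a pro-apoptotic interferon target, by 1.97. GM14446, which belongs to none of the lists, rose by 2.34, from 0.955 ± 0.0647 to 8.89 ± 0.206 RPKM (adjusted p = 7.39e-07). The mean log2 change of the list was 1.24 (SD over members 0.69), and camera, which sets a list against all other genes, gave an adjusted p of 2.97e-40, or adjusted p = 0.0211 with an estimated correlation. Among interferon genes, IFNB1 and IFNL3 were listed at 0 in all 3 DMSO libraries and reached at most 0.127 and 0.0656 RPKM in DZNep. IFNE, picked out after its values were seen, fell from 2.12 ± 0.120 to 0.708 ± 0.101 RPKM (-0.87; adjusted p = 2.84e-04). Fold changes are on the log2(RPKM + 1) scale and understate those of weakly expressed genes. Reads of near-identical family members, among them IFIT, OAS, class I and histone genes, cannot be told apart here.

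**Figure D1:**
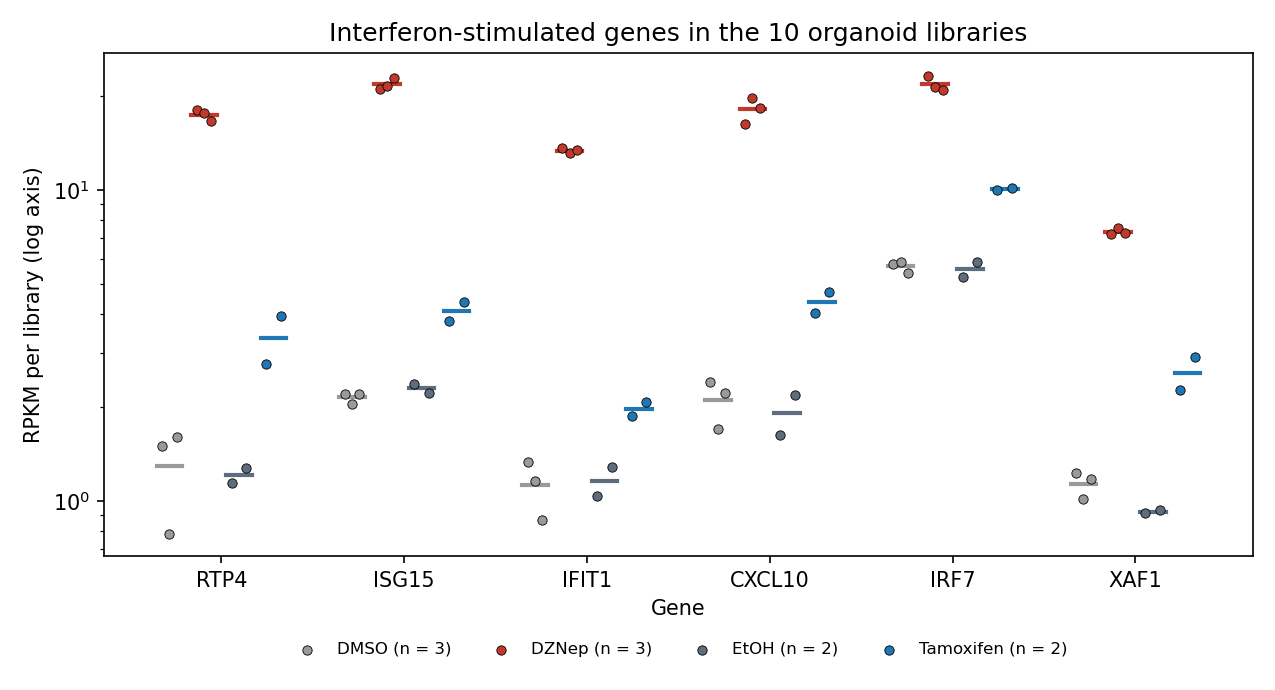
RPKM on a log axis of RTP4, ISG15, IFIT1, CXCL10, IRF7 and XAF1 in each of the 10 libraries, with a point per library and a line at each group mean. ISG15 averaged 2.16 RPKM in DMSO and 21.9 in DZNep, and 2.30 in EtOH and 4.08 in Tamoxifen.

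Genes of MHC class I antigen presentation also rose. Of 21 tested members, 16 rose and 0 fell (18 and 0 adjusted over the list alone), with a mean log2 change of 0.51 (camera adjusted p = 1.53e-10; adjusted p = 0.0423 with an estimated correlation). TAP1, a subunit of the peptide transporter, went from 6.87 ± 0.292 to 15.3 ± 0.313 RPKM (log2 change 1.05, SE 0.0483; adjusted p = 1.07e-05). H2-T23, a non-classical class I molecule, went from 60.1 ± 2.02 to 98.3 ± 2.13 RPKM (0.70, SE 0.0476; adjusted p = 7.52e-05). Sensors of double-stranded RNA and cytosolic DNA followed, with 14 of 22 members up and 0 down (14 and 1 adjusted over the list alone), a mean of 0.38, a camera adjusted p of 2.51e-06 and adjusted p = 0.0348 with an estimated correlation. This list shares 8 tested members with the interferon list. DHX58, a RIG-I-like receptor, rose by 1.35 (SE 0.0688), from 0.871 ± 0.0243 to 3.78 ± 0.312 RPKM, and ZBP1, a sensor of Z-form nucleic acids, by 1.36 (SE 0.0763), from 0.424 ± 0.0702 to 2.65 ± 0.192 RPKM.

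Among checkpoint ligands and T cell chemokines, 6 of 8 members rose and 0 fell, by the test over all genes and adjusted over the list alone (mean 0.70, camera adjusted p = 0.00119; adjusted p = 0.129 with an estimated correlation). They were CXCL10, LGALS9, CCL5, CD80, CXCL16 and ICAM1. CXCL10 and LGALS9, with the largest rises, also belong to the interferon list, and the median of the 8 members was 0.29. LGALS9, a galectin that binds an inhibitory T cell receptor, went from 3.99 ± 0.884 to 13.3 ± 0.241 RPKM (log2 change 1.54, SE 0.110; adjusted p = 1.06e-04). CCL5, a T cell chemokine, rose by 0.78, the costimulatory ligand CD80 by 0.30, CXCL16 by 0.28 and the adhesion molecule ICAM1 by 0.19. PVR (-0.06, adjusted p = 0.463) and IL15 (-0.02, adjusted p = 0.927) did not pass. CD274, which encodes PD-L1, lay below the expression filter at 0.139 ± 0.0160 RPKM in DMSO and 0.413 ± 0.0582 in DZNep. With no filter, its log2 change of 0.31 had an adjusted p of 0.00384. CD274 was picked out after its values were seen. In the NF-kB and TNF response list, 9 of 23 members rose and 3 fell, also adjusted over the list alone, with a mean of 0.26 and a camera adjusted p of 0.0610. That list passed without DMSO 2 (adjusted p = 0.0180), DMSO 3 (0.0379) or DZNep 3 (0.0348), and after quantile normalization (0.0447). Only 1 of its members fell when any of DMSO 2, DMSO 3 or a DZNep library was left out.

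EZH2 itself was lower after DZNep. It went from 29.1 ± 1.78 to 23.8 ± 1.19 RPKM (n = 3 each), a log2 change of -0.28 (SE 0.0612; limma adjusted p = 0.0142). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Without DMSO 2 the change was -0.26 and its adjusted p 0.0641. Of 11 PRC2 members, EZH2, SUZ12 and PHF19 fell and EZH1 rose, and the same 1 and 3 passed adjusted over the list alone. The list as a whole did not pass camera (mean -0.04, adjusted p = 0.376). SUZ12, a core subunit, went from 22.6 ± 0.612 to 19.11 ± 0.345 RPKM (-0.23, SE 0.0445; adjusted p = 0.00851). EZH1, the second methyltransferase of the complex, went from 14.4 ± 1.03 to 18.0 ± 1.22 RPKM (0.31, SE 0.0689; adjusted p = 0.0142). PHF19, an accessory subunit, had a log2 change of -0.30 (adjusted p = 0.0189). Without DMSO 2 only 1 member fell.

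Canonical PRC2 target genes, developmental regulators that the complex commonly represses, were lower as a group where they passed the filter. Of 82 members 38 did so, and targets below the filter were not tested. Of 38 tested members 3 rose and 11 fell, also adjusted over the list alone, with a mean of -0.11 and a camera adjusted p of 0.0126 (adjusted p = 0.716 with an estimated correlation). The call was lost with a filter of 5 RPKM (adjusted p = 0.138). BMP7 went from 14.95 ± 0.418 to 11.6 ± 0.464 RPKM (-0.34, SE 0.0488; adjusted p = 0.00267) and BMP2 from 11.6 ± 1.33 to 7.29 ± 0.694 (-0.61, SE 0.0896; adjusted p = 0.00295), both encoding bone morphogenetic proteins. The falls numbered 6 without DMSO 2 and 7 without DMSO 3 or DZNep 2. Germline genes usually silenced by DNA methylation had 0 members above the filter, the highest being STAG3 at 0.861 RPKM. In the methionine and S-adenosylmethionine cycle, the pathway that DZNep targets, 3 of 18 members rose and 0 fell (3 and 0 adjusted over the list alone), with a mean of 0.14 and a camera adjusted p of 0.327. Those were CBS (log2 change 1.23), ADK (0.57) and MTR (0.37), with enzymes of transsulfuration, adenosine phosphorylation and methionine synthesis as their products. Without DMSO 1 there were 6.

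Cell cycle genes were lower on average, with overlap between the groups. The mean of the S phase list was 4.15 in DMSO 3 and 4.22 in DZNep 3 on the log2 scale, and that of the G2 and M phase list 4.61 and 4.65. Of 44 S phase genes 1 rose and 7 fell, and of 45 G2 and M phase genes 1 rose and 14 fell, both also adjusted over the list alone. The means were -0.13 (camera adjusted p = 2.84e-04) and -0.15 (1.33e-05), and both calls were lost with adjusted p = 0.731 with an estimated correlation. E2F8, a repressor of E2F targets, went from 13.0 ± 0.515 to 9.27 ± 0.286 RPKM (-0.44; adjusted p = 8.46e-04) and the replication licensing factor CDT1 from 22.3 ± 1.15 to 16.6 ± 0.498 (-0.41; adjusted p = 0.00166). CENPE, a kinetochore motor, changed by -0.39 and the spindle protein TACC3 by -0.32. The member of the second list that rose was the proliferation marker MKI67 (0.18, adjusted p = 0.0334). S phase falls numbered 3 without DMSO 2, 4 without DZNep 1 or DZNep 2, and 13 without DMSO 3. Those of the G2 and M phase list numbered 6, 8 and 7 without DMSO 2, DZNep 1 and DZNep 2.

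MYC targets and ribosome biogenesis genes were higher, with 18 of 46 members up and 0 down (23 and 0 adjusted over the list alone), a mean of 0.18 and a camera adjusted p of 1.98e-04, but adjusted p = 0.731 with an estimated correlation. ODC1, which starts polyamine synthesis, went from 26.4 ± 3.54 to 42.9 ± 3.56 RPKM (0.69; adjusted p = 0.00260) and NOP2, a ribosomal RNA methyltransferase, from 25.2 ± 2.05 to 33.9 ± 1.05 (0.42; adjusted p = 0.00355). The number that rose was 29 without DMSO 1, 5 without DMSO 2, 9 without DMSO 3, 6 without DZNep 2 and 8 without DZNep 3. Targets of p53 rose, 16 of 31 with 0 down (21 and 0 adjusted over the list alone), with a mean of 0.25, a camera adjusted p of 5.35e-07 and adjusted p = 0.0348 with an estimated correlation. GDF15, a stress-induced cytokine, rose by 0.63 (9.27 ± 0.460 to 14.8 ± 0.628 RPKM; adjusted p = 2.81e-04) and EDA2R, a receptor of the TNF receptor family, by 0.58 (3.22 ± 0.179 to 5.30 ± 0.240 RPKM; adjusted p = 5.60e-04). Without DZNep 2, 10 of the p53 targets rose.

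Beyond the lists, the deepest falls included HR, a transcriptional corepressor of skin and hair follicles, from 41.4 ± 5.22 to 12.7 ± 0.988 RPKM (-1.62, SE 0.0965; adjusted p = 3.72e-05). HIST1H2BJ, a histone H2B gene, went from 5.32 ± 0.438 to 1.10 ± 0.206 RPKM (-1.59, SE 0.0902; adjusted p = 3.00e-05), and FOSB, a subunit of the AP-1 transcription factor, from 39.6 ± 5.29 to 15.96 ± 2.49 (-1.26, SE 0.125; adjusted p = 5.29e-04). RAB26OS, annotated opposite RAB26, changed by -1.27 (SE 0.140; adjusted p = 7.85e-04), and whether the authors' quantification used strand is not known. The microRNA gene MIR27A fell from 789 ± 327 to 301 ± 53.7 RPKM (-1.32, SE 0.263; adjusted p = 0.00966). Its call was lost with robust variance estimates (adjusted p = 0.0542) and in a joint fit of all 10 libraries (0.0599). Such short RNA genes are poorly measured in mRNA libraries.

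Epithelial identity lists moved in both directions. Androgen receptor targets had 6 up and 2 down of 26 (mean 0.07, camera adjusted p = 0.679), luminal markers 5 up and 2 down of 19 (0.09, 0.679) and basal markers 8 up and 5 down of 21 (0.14, 0.743). The basal list's median was -0.055, opposite in sign to its mean, and 9 rose and 7 fell adjusted over the list alone, where the first pair of lists kept 6 and 2, and 5 and 2. Epithelial-mesenchymal transition genes had 7 up and 5 down of 24 (8 and 5 adjusted over the list alone; mean 0.13, camera adjusted p = 0.348). In the ATF4 and unfolded protein response list 8 rose and 4 fell of 33, also adjusted over the list alone (0.04, 0.679). Cholesterol biosynthesis had 1 of 24 up (0 adjusted over the list alone), a mean of 0.01 and a camera direction of down (0.679). Immediate early and heat shock genes had 3 up and 8 down of 23 (4 and 8 adjusted over the list alone; -0.14, 0.123). Without DMSO 2, 3 rose and 0 fell among androgen receptor targets, 6 and 3 among basal markers, 2 and 2 in the ATF4 list and 7 and 1 in the transition list. Without DZNep 2 the first 3 of these gave 3 and 0, 6 and 3, and 2 and 4.

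Markers of other cell types were mostly too low to test. Of the fibroblast and smooth muscle list 3 members passed the filter (mean 0.57, camera adjusted p = 0.265). DCN, a matrix proteoglycan, rose by 0.92 (2.77 to 6.11 RPKM), smooth muscle actin ACTA2 rose by 1.11 (0.692 to 2.62 RPKM) and FBLN1 changed by -0.30 (adjusted p = 0.0293), a call lost without DMSO 1 (0.0665), DMSO 2 (0.0655), DMSO 3 (0.0621), DZNep 1 (0.0520) or DZNep 3 (0.0727). The neuroendocrine list kept ENO2, which fell (-0.48; adjusted p = 0.0112), and SOX2 (0.16, 0.0694; 0.0284 without DMSO 1). The immune list kept CD68 (adjusted p = 0.0980) and CD52 (0.266), and the endothelial list EGFL7 (0.161), and lists of under 3 members were not tested. MHC class II genes had 0 members above the filter, the highest being H2-DMA at 0.476 RPKM.

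Over all 11143 genes tested with limma, 1850 rose and 1238 fell after DZNep, 3088 in all, and 4652 had an unadjusted p under 0.05. Most changes were small: 86 rose and 13 fell by at least 2-fold, and the median size of the called changes was 0.298 on the log2 scale. The excess of rises depended on the scaling: 1635 rose and 1635 fell after quantile normalization, and 1652 and 1469 with trimmed mean scaling. The total was 1522 without DMSO 2 and 1755 without DZNep 2. Of 20 lists tested, 9 passed camera and 4 did so with an estimated correlation, namely interferon-stimulated genes, MHC class I, sensing and p53 targets. With fry, a test of whether a list's genes move one way, 10 passed. Those were the same 4, checkpoint ligands, the NF-kB list (adjusted p = 0.00632), the methionine cycle (0.0204), and fibroblast (0.0140) and basal markers (0.0473) as higher, and the PRC2 complex (0.0204) as lower. PRC2 targets (0.0641), S phase genes (0.1904), G2 and M phase genes (0.140) and MYC targets (0.0941) did not pass fry.

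**Figure D2:**
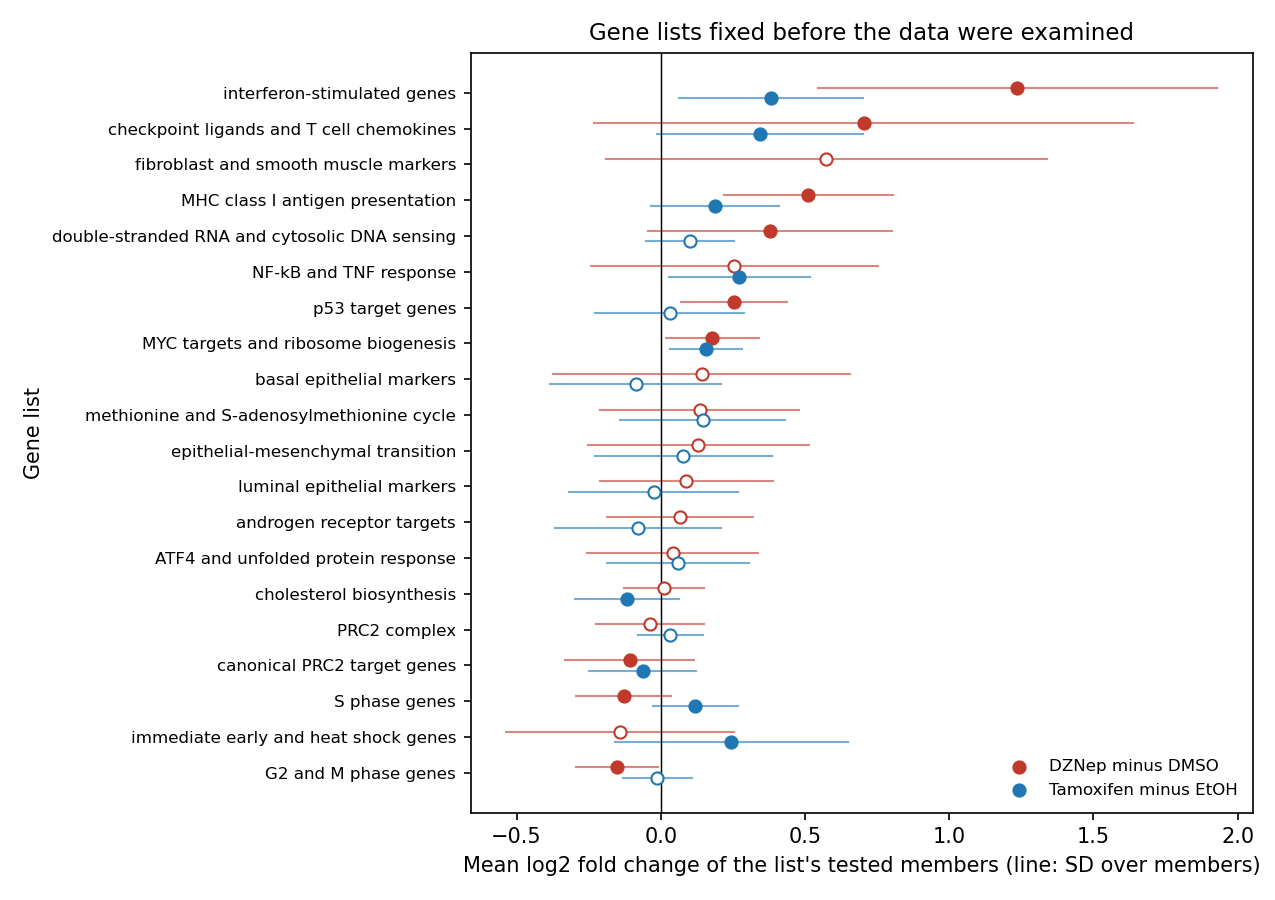
Mean log2 change of the tested members of the lists tested with camera, 20 with DZNep and 19 with Tamoxifen, with bars of 1 SD over members, filled where camera with a preset correlation passed and open where it did not. The interferon list lies at 1.24 with DZNep and 0.38 with Tamoxifen, and the PRC2 complex at -0.04 and 0.03.

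The genetic experiment asked the same of organoids in which Tamoxifen activates Cre. EZH2, the floxed gene, was not lower in the libraries labelled Tamoxifen. It measured 31.0 ± 4.25 RPKM in EtOH and 32.6 ± 0.822 in Tamoxifen (n = 2 each), a log2 difference of 0.08 (SE 0.0986; limma adjusted p = 0.635). An exact two-sided permutation test gave p = 1, where the smallest possible is 0.333. A value for the whole gene keeps exons outside the floxed part, so it does not check the deletion. Of 11 PRC2 members 0 passed limma, over all genes or adjusted over the list alone (mean 0.03, camera adjusted p = 0.976). MTF2 (-0.18, adjusted p = 0.140) and RBBP4 (0.21, adjusted p = 0.171) had the smallest p-values, and without EtOH 2 RBBP4 passed at 0.0478.

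Interferon-stimulated genes were higher in the libraries labelled Tamoxifen. Of 45 tested members 11 rose and 0 fell (30 and 1 adjusted over the list alone), with a mean log2 change of 0.38 (SD over members 0.32) and a camera adjusted p of 1.60e-11, but adjusted p = 0.637 with an estimated correlation. IRF7, the transcription factor that drives interferon production, went from 5.56 ± 0.417 to 10.1 ± 0.140 RPKM (0.76, SE 0.0665; adjusted p = 0.0263). LGALS3BP, a secreted glycoprotein, went from 18.9 ± 1.56 to 36.8 ± 3.52 RPKM (0.93; adjusted p = 0.0276), OAS1A, an oligoadenylate synthetase, from 3.73 ± 0.321 to 8.07 ± 0.995 (0.94; adjusted p = 0.0305), and USP18, the protease that removes ISG15, from 16.2 ± 0.203 to 23.7 ± 0.719 (0.52; adjusted p = 0.0305). ISG15, RTP4, XAF1, CXCL10, IRF9, BST2 and IRGM1 were the others that rose. Of the list 4 members rose without Tamoxifen 1, 0 without Tamoxifen 2 and 18 without EtOH 2. Without Tamoxifen 2 the adjusted p was 0.129 for IRF7, 0.114 for LGALS3BP, 0.116 for OAS1A and 0.228 for USP18. Without Tamoxifen 1 it was 0.0954 for IRF7 and 0.121 for USP18. With no expression filter, IRF7, LGALS3BP, OAS1A and USP18 did not pass.

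In the MHC class I list 2 of 20 members rose and 0 fell (11 and 0 adjusted over the list alone), with a mean of 0.19 and a camera adjusted p of 0.00341 (adjusted p = 0.698 with an estimated correlation). H2-Q4, a class I molecule, went from 11.7 ± 0.394 to 17.6 ± 0.832 RPKM (0.56; adjusted p = 0.0305) and PSMB10, an immunoproteasome subunit, from 10.3 ± 0.114 to 14.0 ± 0.542 (0.41; adjusted p = 0.0395). For H2-Q4 the adjusted p was 0.162 without Tamoxifen 1 and 0.167 without Tamoxifen 2. For PSMB10 it was 0.0530 without EtOH 1, 0.181 without Tamoxifen 1, 0.324 without Tamoxifen 2 and 0.0528 without a mean trend. Without EtOH 2, 6 members rose and 1 fell. In the sensing list 1 of 20 rose (also 1 adjusted over the list alone; mean 0.10, camera adjusted p = 0.121), and that list passed without EtOH 1 (0.0264) and with no filter (0.0381). The member was IKBKE, a kinase that activates interferon regulatory factors, at 16.7 ± 0.161 RPKM in EtOH and 21.4 ± 0.421 in Tamoxifen (0.34; adjusted p = 0.0486), a call lost without EtOH 1 (0.0692), Tamoxifen 1 (0.234) or Tamoxifen 2 (0.368). ADAR, the editor of double-stranded RNA, went from 9.34 to 12.4 RPKM and did not pass (0.38, adjusted p = 0.0823).

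Of 8 checkpoint ligands and chemokines 2 rose and 0 fell (6 and 1 adjusted over the list alone), with a mean of 0.35 and a camera adjusted p of 0.0201 (adjusted p = 0.637 with an estimated correlation; 0.0756 without EtOH 2). ICAM1 went from 10.2 ± 0.145 to 14.9 ± 0.902 RPKM (0.51; adjusted p = 0.0344) and CXCL10 from 1.91 ± 0.395 to 4.36 ± 0.468 (0.88; adjusted p = 0.0395). Leaving out Tamoxifen 1 or Tamoxifen 2 ended both calls, with adjusted p-values of 0.119 and 0.242 for ICAM1 and 0.117 and 0.230 for CXCL10. The other members were LGALS9 (0.54, adjusted p = 0.0913), CCL5 (0.60, 0.160), CXCL16 (0.25, 0.177), PVR (0.18, 0.133), IL15 (0.02, 0.873) and CD80 (-0.23, 0.148). CD274 measured 0.116 ± 0.0363 RPKM in EtOH and 0.124 ± 0.00759 in Tamoxifen, below the filter. In the NF-kB and TNF response list 3 of 23 rose and 0 fell (10 and 0 adjusted over the list alone), with a mean of 0.27 and a camera adjusted p of 3.47e-04 (adjusted p = 0.637 with an estimated correlation). CSF1, a macrophage growth factor, went from 5.57 ± 0.0435 to 7.95 ± 0.117 RPKM (0.45; adjusted p = 0.0344). LIF, a cytokine of the interleukin 6 family, rose by 0.70 (adjusted p = 0.0381). Both were lost without Tamoxifen 1 (0.181 and 0.108) or Tamoxifen 2 (0.273 and 0.230), and 5 members of the list rose without EtOH 1.

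Canonical PRC2 targets above the filter, 36 of 82, were again lower as a group. Of these 0 rose and 1 fell (1 and 6 adjusted over the list alone). Their mean was -0.06, with a camera adjusted p of 0.00628, but adjusted p = 0.637 with an estimated correlation. HOXA9, a homeobox gene, went from 29.7 ± 0.945 to 22.2 ± 0.869 RPKM (-0.40; adjusted p = 0.0445), a call lost without EtOH 1 (0.0606), Tamoxifen 1 (0.197) or Tamoxifen 2 (0.335). CDKN1C, a cyclin-dependent kinase inhibitor, had a log2 change of -0.50 (adjusted p = 0.0523; 0.0389 without EtOH 2).

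S phase genes (mean 0.12, camera adjusted p = 0.0201) and MYC targets and ribosome biogenesis genes (0.16, 7.07e-04) lay higher as groups, with adjusted p = 0.888 and adjusted p = 0.848 with an estimated correlation. In limma 0 of 44 and 0 of 46 members passed, over all genes or adjusted over the list alone, and without EtOH 2 there were 4 S phase calls, 3 of them rises, and 8 MYC target rises. The S phase call was lost without EtOH 1 (0.209) or Tamoxifen 2 (0.668), and the list's mean was 4.33 in EtOH 2 and 4.31 in Tamoxifen 1. The S phase mean was 4.22 in EtOH 1 and 4.48 in Tamoxifen 2, so within either replicate number Tamoxifen lay higher. CCNE2, a cyclin, changed by -0.43 (adjusted p = 0.0625) and UNG, a uracil glycosylase, by 0.37 (0.0835). IPO4, an importin, changed by 0.29 (0.0711) and DCTPP1, a nucleotide phosphatase, by 0.32 (0.105). Without EtOH 2, CCNE2 (0.0450), IPO4 (0.0460) and DCTPP1 (0.0396) passed. Among G2 and M phase genes 0 of 45 passed, over all genes or adjusted over the list alone (-0.01, camera adjusted p = 0.155), and the list was lower without EtOH 1 (0.00272) or Tamoxifen 2 (3.99e-04).

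Cholesterol biosynthesis genes were lower as a group, with 0 up and 1 down of 24 (0 and 6 adjusted over the list alone), a mean of -0.12 and a camera adjusted p of 0.00105 (adjusted p = 0.790 with an estimated correlation; 0.196 without EtOH 2). The list's mean was 5.40 in EtOH 1 and 5.41 in Tamoxifen 2. It was 5.56 in EtOH 2 and 5.31 in Tamoxifen 1, so within either replicate number Tamoxifen lay lower. IDI1, an isomerase of the mevalonate pathway, went from 91.3 ± 6.21 to 58.3 ± 3.17 RPKM (-0.64; adjusted p = 0.0330; 0.167 without Tamoxifen 1 and 0.170 without Tamoxifen 2). SC5D, a sterol desaturase, changed by -0.31 (adjusted p = 0.0572; 0.0478 without EtOH 2). Immediate early and heat shock genes lay higher, with 2 up and 1 down of 23 (11 and 1 adjusted over the list alone), a mean of 0.24 and a camera adjusted p of 0.00478 (adjusted p = 0.637 with an estimated correlation; 0.0649 without EtOH 2). FOSB and JUN, both subunits of AP-1, rose, JUN from 88.9 ± 4.14 to 125 ± 7.54 RPKM (0.49; adjusted p = 0.0439), and KLF4, a transcription factor of differentiating epithelia, fell from 71.7 ± 0.0534 to 48.1 ± 0.952 (-0.57; adjusted p = 0.0263). JUN was lost without EtOH 1 (0.0560), Tamoxifen 1 (0.167) or Tamoxifen 2 (0.323), KLF4 without Tamoxifen 1 (0.132) or Tamoxifen 2 (0.170), and FOSB without Tamoxifen 1 (0.0956) or Tamoxifen 2 (0.230).

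The deepest falls in the libraries labelled Tamoxifen included TFF1, MT4, KLRA33 and PPBP. TFF1, a trefoil peptide of mucosal secretions, went from 170 ± 5.80 to 34.8 ± 3.74 RPKM (-2.26, SE 0.0861; adjusted p = 0.00439). MT4, a metallothionein of stratified squamous epithelium, went from 5.22 ± 0.693 to 0.254 ± 0.360 RPKM (-2.34; adjusted p = 0.0263; 0.0544 with a pseudocount of 0.1). KLRA33 went from 5.29 ± 0.528 to 0.791 ± 0.239 RPKM (-1.82; adjusted p = 0.0170) and PPBP, a CXC chemokine, from 39.9 ± 4.59 to 12.9 ± 0.765 (-1.55; adjusted p = 0.0128). The other genes with the largest changes were short RNA genes or a pseudogene. MIR677 was listed at 462 and 216 RPKM in EtOH and at 0 in both Tamoxifen libraries (adjusted p = 0.00439; 0.139 in the joint fit). MIR25 was listed at 0 in EtOH and at 92.5 and 94.8 RPKM in Tamoxifen (adjusted p = 2.38e-06). Such switches also arose within the DMSO group. MIR25 was at 106 and 103 RPKM in DMSO 1 and DMSO 2 and at 0 in DMSO 3. MIR677 was at 0 in DMSO 1 and DMSO 2 and at 631 RPKM in DMSO 3. MIR3101 (adjusted p = 0.0305) and MIR24-2 (0.0270) were also listed at 0 in EtOH, and both were lost with robust variance estimates (0.121 and 0.108) and in the joint fit (0.0822 and 0.132). APOO-PS reached 10.3 RPKM in Tamoxifen from at most 2.04e-05 in EtOH (adjusted p = 0.00879). MIR8094 went from 18.0 ± 8.41 to 98.8 ± 35.2 RPKM (2.42; adjusted p = 0.0483), and lost its call without Tamoxifen 1 (0.167) or Tamoxifen 2 (0.116).

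The remaining lists did not pass with Tamoxifen. The methionine cycle had 0 calls among 17 members in limma, over all genes or adjusted over the list alone (mean 0.15, camera adjusted p = 0.424). Androgen receptor targets had 0 up and 3 down of 26 (1 and 4 adjusted over the list alone; -0.08, 0.110), and passed as lower without Tamoxifen 1 (0.0164). Those that fell included ELL2, an elongation factor, and HPGD, which degrades prostaglandins. Luminal markers had 0 up and 2 down of 19 (1 and 2 adjusted over the list alone), the keratin KRT4 among them, with a mean of -0.02, a median of 0.022 and a camera adjusted p of 0.697. Basal markers had 0 up and 2 down of 21 (2 and 7 adjusted over the list alone), the keratin KRT14 and the water channel AQP3, with a mean of -0.09, a median of 0.003 and a camera adjusted p of 0.110, which passed without EtOH 2 (0.0348) and in the joint fit (0.0396). Targets of p53 had 1 up, GDF15, and 1 down, TRP53INP1, of 31 (2 and 3 adjusted over the list alone; 0.03, 0.729). The ATF4 list had 0 up and 1 down of 33 (2 and 1 adjusted over the list alone; 0.06, 0.857). Epithelial-mesenchymal transition had 1 of 23 up, the collagen gene COL4A1, and 0 down (7 and 4 adjusted over the list alone; 0.08, 0.669). The neuroendocrine list kept SOX2, which fell from 19.3 ± 0.512 to 14.4 ± 0.113 RPKM (-0.40; adjusted p = 0.0381; 0.220 without Tamoxifen 1 and 0.281 without Tamoxifen 2), and ENO2 (0.211). The fibroblast list kept DCN (0.633) and FBLN1 (0.450), the immune list CD68 (0.857) and CD52 (0.156), and the endothelial list EGFL7 (0.737). MHC class II and germline genes had 0 members above the filter.

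Of 11123 genes tested with limma, 77 rose and 153 fell in the libraries labelled Tamoxifen, 230 in all, and 2831 had an unadjusted p under 0.05. By at least 2-fold 8 rose and 18 fell, of which 5 were short RNA genes. The total was 977 without EtOH 2 (592 up and 385 down), 50 without Tamoxifen 1 (29 and 21) and 37 without Tamoxifen 2 (23 and 14), so that rises outnumbered falls in each, and 27 and 18 of the 230 genes stayed called in the last pair. With no expression filter only 1 gene passed, where 3181 had an unadjusted p under 0.05. Of 19 lists tested 9 passed camera, and 0 did so with an estimated correlation or with fry. Without Tamoxifen 2, members of the interferon, MHC class I, sensing, checkpoint, NF-kB, PRC2 target, androgen receptor, luminal, basal, p53, ATF4, cholesterol, transition and immediate early lists gave 0 calls in limma. Without Tamoxifen 1 these lists gave 4 interferon, 1 ATF4 and 1 immediate early call, and 0 in the others.

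Setting the experiments side by side asked whether chemical and genetic inhibition changed the same genes. The interferon list rose more with DZNep: over the 45 members tested in both, the mean log2 change was larger by 0.85 (camera adjusted p = 3.50e-27; adjusted p = 0.0140 with an estimated correlation), and 38 members differed, all larger with DZNep. RTP4 (3.03 with DZNep, 0.96 with Tamoxifen), CXCL10 (2.62 and 0.88), ISG15 (2.86 and 0.62) and XAF1 (1.97 and 0.89) rose in both. Their differences were 2.07 (SE 0.219; adjusted p = 3.24e-04), 1.74 (SE 0.170; adjusted p = 2.27e-04), 2.24 (SE 0.0928; adjusted p = 1.21e-06) and 1.07 (SE 0.114; adjusted p = 3.30e-04). Their calls with Tamoxifen (adjusted p = 0.0462 for RTP4, 0.0395 for ISG15, 0.0344 for XAF1) were lost without Tamoxifen 2 (0.170, 0.255 and 0.170). Without Tamoxifen 1 ISG15 (0.111) and XAF1 (0.0535) were lost, and without EtOH 1 RTP4 (0.0692). GM14446 rose with DZNep (2.34) and measured 0.37 with Tamoxifen (adjusted p = 0.0893), a difference of 1.97 (adjusted p = 1.21e-06). KRT13, a keratin of stratified epithelium, rose by 1.51 with DZNep and changed by -1.54 with Tamoxifen, a difference of 3.05 (SE 0.110; adjusted p = 5.94e-07). PPBP likewise went up by 1.78 and changed by -1.55, differing by 3.33 (SE 0.148; adjusted p = 1.21e-06).

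MHC class I genes (mean difference 0.33, camera adjusted p = 4.37e-05; adjusted p = 0.180 with an estimated correlation), sensing genes (0.18, 0.0108; adjusted p = 0.146 with an estimated correlation) and p53 targets (0.22, 9.09e-04; adjusted p = 0.146 with an estimated correlation) moved further up with DZNep. S phase genes (-0.25, 4.37e-05; adjusted p = 0.805 with an estimated correlation), G2 and M phase genes (-0.14, 0.0259; adjusted p = 0.878 with an estimated correlation) and immediate early genes (-0.38, 0.0123; adjusted p = 0.805 with an estimated correlation) lay lower with DZNep. The G2 and M phase call was lost without DMSO 1 (0.183), DZNep 1 (0.204), EtOH 1 (0.164) or Tamoxifen 2 (0.306), and the immediate early call without EtOH 2 (0.0588). Cholesterol biosynthesis (0.13, camera adjusted p = 0.102) passed without DMSO 1 (0.0137), EtOH 1 (0.00645) or Tamoxifen 2 (0.0215). Checkpoint ligands (0.337), the NF-kB list (0.372), the PRC2 complex (0.576), PRC2 targets (0.912) and MYC targets (0.835) did not differ past the threshold, nor did the remaining lists. For the ATF4 list the camera direction was up and the mean -0.02 (0.888).

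**Figure D3:**
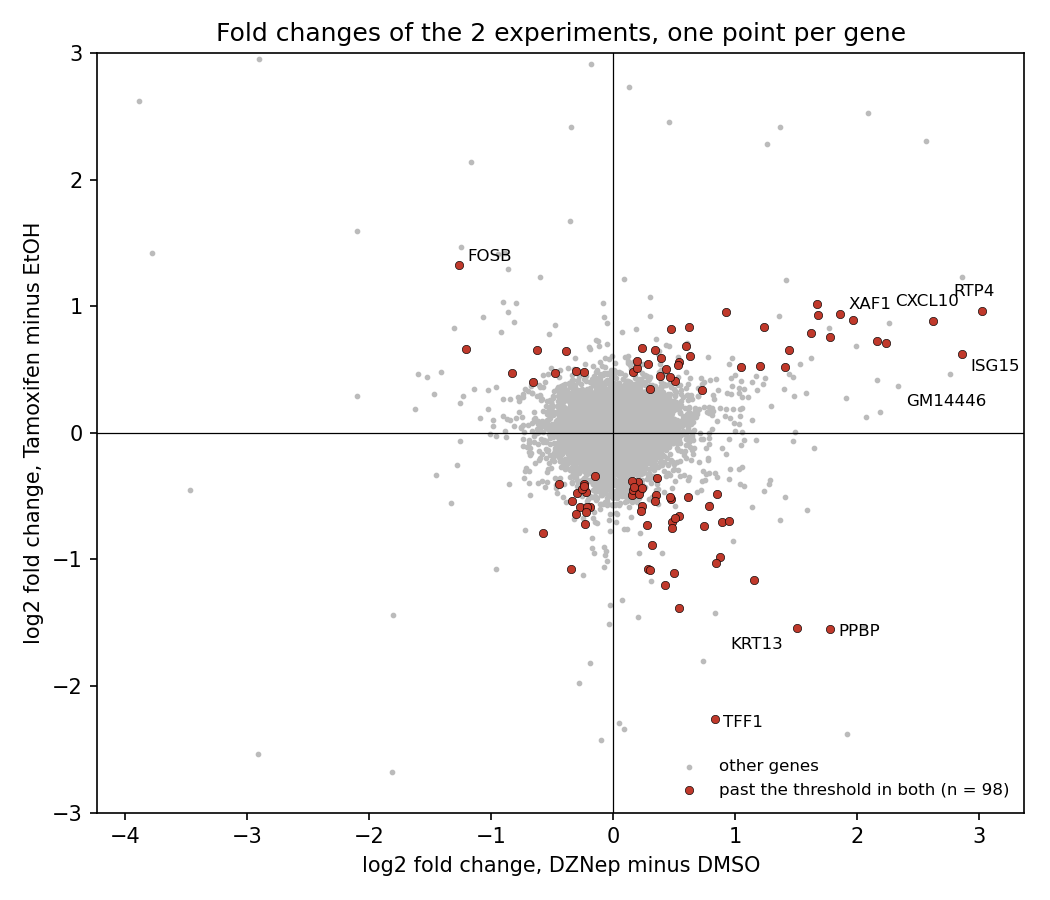
Log2 change of 10976 genes with DZNep (horizontal) against Tamoxifen (vertical), with the 98 genes past the threshold in both in red and 18 genes beyond the vertical axis not drawn. RTP4 lies at 3.03 and 0.96, and KRT13 at 1.51 and -1.54.

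Of 10994 genes tested in both, 2190 differed between the experiments in limma, 1179 of them larger and 1011 smaller with DZNep. That number was 924 without Tamoxifen 2, 1289 without Tamoxifen 1, 1316 without EtOH 1 and 1393 without DMSO 2. Genes that rose in both numbered 36, where independent lists would share 12.5 (Fisher's exact p = 2.93e-10), and genes that fell in both numbered 16, where 17.2 would be shared (p = 0.897). Another 37 rose with DZNep and fell with Tamoxifen (25.1 for independent lists; Fisher's exact p = 0.0150), and 9 did the reverse (8.52; Fisher's exact p = 0.855). Fisher's test counts each gene as independent, which genes that move together are not. Its p-values therefore do not measure agreement between the experiments. With the interferon list taken out, 25 genes rose in both. The 36 became 156 without EtOH 2, 4 without Tamoxifen 1 and 0 without Tamoxifen 2. The 16 became 43, 1 and 0 in the same order, and 5 without DMSO 2 and 8 without DZNep 2. The 37 became 73, 11 and 8, and the 9 became 74, 2 and 0. Without short RNA genes the 37 were 78 and the 9 were 44. Calls with Tamoxifen also grew there, from 76 up and 153 down to 294 and 415. Longer lists share more genes even if independent. Numbers for independent lists were not worked out for these alternatives, so their counts do not show a larger or smaller excess. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.0116 and Spearman's rho 0.0350. Without DMSO 3 r was -0.0521, and without the short RNA genes 0.0509. Genes called higher with DZNep, a planned set, averaged 0.047 with Tamoxifen (1807 tested, camera adjusted p = 0.390, fry 0.171). Those called lower, also planned, averaged 0.033 (1233 tested, camera adjusted p = 0.787, fry 0.193). In sets not planned, genes that rose at least 2-fold averaged 0.23 (71 tested, camera adjusted p = 7.66e-05, fry 0.0289). With an estimated correlation that camera adjusted p was 0.481. Once the interferon list was taken out their mean was 0.041 (44 tested, camera adjusted p = 0.787). Genes that fell at least 2-fold averaged 0.23 as well (13 tested, camera adjusted p = 0.171, fry 0.171). A mean of 0.23 alone therefore does not show a shared direction.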

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

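The tests of the added squamous, mucosal and urothelial lists, and all tests of technical explanations except the comparison of EtOH 1 with the DMSO libraries, were chosen only after the results were seen. Groups of 2 or 3 libraries are too small for a test of single libraries that stand apart.

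Interferon-stimulated genes were higher in both experiments, by 0.85 more on the log2 scale with DZNep. The Tamoxifen camera call was lost with an estimated correlation (adjusted p = 0.637), and the list did not pass fry either (adjusted p = 0.0813). Without Tamoxifen 2 the list's mean was 0.34. EtOH 1, which stands apart in the genetic experiment, is argued against as the cause, since the list's mean without it was 0.38. RNA of immune cells is also argued against: the higher of the median levels of 23 immune markers in the treated libraries was 0.00165 RPKM, and 19 stayed under 0.1 RPKM, where the list's members gained a median of 6.64 RPKM with DZNep and 1.78 with Tamoxifen. An effect of Tamoxifen itself or of active Cre stays open, since 0 libraries had Tamoxifen without the transgene. DZNep blocks S-adenosylhomocysteine hydrolase, and the design has no library that separates other effects of this block from loss of EZH2 function. Loss of EZH2 function in both experiments is the explanation the design names, and it may account for the shared part only as a hypothesis. It was not tested: EZH2 RNA was not lower in the libraries labelled Tamoxifen, and whole-gene values do not check the deletion. PRC2 targets above the filter, 38 and 36 of 82, were not raised, with means of -0.11 with DZNep and -0.06 with Tamoxifen. Targets below the filter were not tested, so these means cannot tell whether weakly expressed targets rose.

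Squamous differentiation genes fell in the libraries labelled Tamoxifen (mean -0.59, 15 of 31 down, camera adjusted p = 1.60e-20; adjusted p = 0.223 with an estimated correlation) and rose with DZNep (0.35, 21 up and 6 down of 37, adjusted p = 5.84e-04; adjusted p = 0.297 with an estimated correlation), a difference of 0.88 (2.31e-14; lost at adjusted p = 0.0605 with an estimated correlation). The library EtOH 1 is argued against as the cause, since the mean without it was -0.58, and 5 members fell without Tamoxifen 2 and 8 without Tamoxifen 1. A fall of basal cells as deep as that of the squamous list is argued against too, as the basal list's median was 0.0031 (SD over members 0.297) where the squamous list's was -0.51. A smaller fall stays open, since the basal list's mean was -0.09, with 2 up and 7 down adjusted over the list alone. Tamoxifen itself and active Cre stay open, with 0 libraries given Tamoxifen without the transgene, and so does the loss of EZH2.

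EtOH 1 went with the 6 chemical libraries, apart from EtOH 2 and both Tamoxifen libraries, in 8 genes by at least 1 on the log2 scale, and 0 genes did so for any other genetic library. RPS27RT was at 0.555 RPKM in EtOH 1 and at 228, 321 and 745 in the other 3, and RPL26 at 1435 against 181, 19.7 and 15.1. Of the 8 genes, 8 were ribosomal protein, pseudogene or short RNA genes, a class drawn up after these genes were seen, so it stays open whether reads of near-identical copies or short genes were handled otherwise in those 3 libraries. Over other genes the smallest mean difference of EtOH 1 to a DMSO library was 0.0829, less than its 0.108 to EtOH 2, but its largest was 0.118 and DMSO libraries differed by up to 0.130. EtOH 1 was nearer than EtOH 2 to DMSO 2 (0.0829 against 0.111) and DMSO 3 (0.0969 against 0.130). To DMSO 1 it was not (0.118 against 0.115). A DMSO library in its place therefore cannot be told apart from an EtOH one by these distances, which also run across 2 tables of unknown common normalization.

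A difference between the 2 experiments in the response to treatment, by the test of the difference itself, brought in 2190 genes. KRT13 differed by 3.05, PPBP by 3.33, ISG15 by 2.24, RTP4 by 2.07, GM14446 by 1.97, CXCL10 by 1.74 and XAF1 by 1.07, all larger with DZNep. Among lists, MHC class I differed by 0.33, sensing by 0.18 and p53 targets by 0.22. Means lower with DZNep were those of S phase genes (-0.25), G2 and M phase genes (-0.14) and immediate early genes (-0.38). With an estimated correlation these 6 calls were lost (adjusted p = 0.180, 0.146, 0.146, 0.805, 0.878 and 0.805 in that order). Mucosal secretory genes differed by 0.83 (camera adjusted p = 0.00510) and urothelial genes by 0.51 (0.00376), both also lost with an estimated correlation (adjusted p = 0.165 and 0.0605).

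For the 3088 genes changed with DZNep, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many, and the highest other split gave 3. With 10 splits a share under 0.05 is not possible. Every other split mixes DMSO and DZNep libraries within an arm, so the treatment effect widens the spread there and holds calls down. Such counts are therefore not those expected without a treatment effect.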

How the results depend on the processing

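Leaving out short RNA genes was chosen only after results were seen. Of the alternatives for named genes and lists other than EZH2 and the interferon list, 1410 kept their direction and side of the threshold, 51 newly passed, 102 no longer passed and 0 reversed. This tally pools both experiments and includes results that did not pass at first. With no filter, 23 of the 24 named genes called with Tamoxifen lost their call, against 0 of the 30 called with DZNep. The DZNep count of 3088 was 1610 with a replicate block and ran from 1522 to 3359 with each library left out. EZH2 with DZNep was -0.28 with the block (adjusted p = 0.0588; 0.0576 for EZH1) and -0.33 to -0.24 with libraries left out. The Tamoxifen count of 230 was 1 with no filter, 348 with trimmed mean scaling, 646 with robust variances, 878 with the block, 1028 in a joint fit, 710 without short RNA genes, and 37 to 977 with libraries left out. With an estimated correlation 4 lists passed for DZNep and 0 for Tamoxifen, also 0 with fry, where the interferon list at 0.38 had adjusted p-values of 0.637 and 0.0813. The difference count of 2190 was 1226 with the block and 924 to 2326 with libraries left out. Genes higher in both (36) were 0 with no filter, 95 with the block, 117 without short RNA genes and 0 to 156 with libraries left out. Genes lower in both (16) were 0, 28, 50 and 0 to 43 in that order, and 38 after quantile normalization. Such overlap counts also move with the number of calls, and numbers for independent lists were not worked out for these alternatives. Pearson's r (0.0116) was 0.0509 without short RNA genes and -0.0521 to 0.0484 with libraries left out, turning negative without DMSO 3 (-0.0521), EtOH 2 (-0.000123) or Tamoxifen 2 (-0.000638). Spearman's rho (0.0350) was 0.0523 with the filter of 5 RPKM and 0.0147 to 0.0722 with libraries left out. Other than by construction (fewer genes or libraries), the cause was not tested.

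The labels do not say that replicate numbers pair the libraries, and the values do not settle it. Over all genes, deviations of same-numbered libraries correlated at 0.0591, 0.0590 and -0.0675 in the chemical experiment and 0.04004 in the genetic one. DMSO 1 correlated best with DZNep 3 (0.0707) and DMSO 3 with DZNep 2 (0.0945). In the genetic experiment the G2 and M phase mean was 4.69 in EtOH 1 and 4.68 in Tamoxifen 1. It was 4.84 in EtOH 2 and 4.83 in Tamoxifen 2. The NF-kB mean did not follow the numbers: 4.08 and 4.03 in EtOH 1 and 2, 4.27 and 4.39 in Tamoxifen 1 and 2. The block gave 878 Tamoxifen calls where the planned fit gave 230. Fits with 1 library left in an arm assume that it varies like the others. Depth per library is unknown, which limits statements on weakly expressed genes.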

Other observations

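The added gene lists and the genes singled out here were chosen after their values were seen. Squamous genes lay higher with DZNep and lower with Tamoxifen, camera calls lost with an estimated correlation (adjusted p = 0.297 and 0.223, and 0.0605 for the difference). The list passed fry (adjusted p = 0.00200 and 0.0170), which does not set it against other genes. With DZNep, KRT10 and KRT1, keratins of cornifying epithelium, rose by 1.59 (12.7 ± 1.28 to 40.4 ± 4.66 RPKM; adjusted p = 3.98e-05) and 1.41 (adjusted p = 7.52e-05), and SCGB1A1, a secretoglobin, rose by 1.91 (7.63 ± 0.526 to 31.5 ± 2.31 RPKM). With Tamoxifen, SLURP1, a secreted protein of keratinocytes, went from 543 ± 13.9 to 218 ± 25.3 RPKM (-1.32; adjusted p = 0.0215), DSG3, a desmosomal cadherin, changed by -1.08 (adjusted p = 0.0128) and KRT16, a keratin of stressed epidermis, by -0.98 (adjusted p = 0.0249). DSG3 (0.29) and KRT16 (0.88) rose with DZNep. CLU, a secreted chaperone, rose in both, from 382 ± 3.13 to 726 ± 31.4 RPKM with DZNep and from 400 ± 59.8 to 769 ± 0.539 with Tamoxifen, where the call was lost without Tamoxifen 1 (adjusted p = 0.142) or Tamoxifen 2 (0.205). Mucosal secretory genes had 5 up and 0 down of 9 with DZNep (mean 0.51, camera adjusted p = 0.0452; adjusted p = 0.298 with an estimated correlation) and 2 up and 3 down of 8 with Tamoxifen (mean -0.25, median 0.12, adjusted p = 0.633; lower with fry at 0.0119). Urothelial genes had 5 up and 1 down of 9 with DZNep (0.30, 0.0452; adjusted p = 0.297 with an estimated correlation) and 0 of 9 past limma with Tamoxifen (-0.21, 0.0167; adjusted p = 0.223 with an estimated correlation). Both DZNep calls lie close to the threshold: without DMSO 3 they were lost at 0.0532, and without DZNep 1 at 0.0512 and 0.0844. The urothelial one was also lost without DMSO 1 (0.0589) or DZNep 2 (0.0541).

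Of 21 basal markers 8 rose and 5 fell with DZNep (camera adjusted p = 0.743), and 6 and 3 without DMSO 2 or DZNep 2. LGALS7 (1.59), KRT17 (1.04), KRT14 (0.85), DST (0.57), KRT5 (0.42), SNAI2 (0.30), KRT15 (0.24) and NRG1 (0.19) rose, and JAG2 (-0.49), ITGB4 (-0.36), LAMB3 (-0.32), ITGA6 (-0.29) and CDH3 (-0.24) fell. The genes GSDMC2 (20.5 ± 2.68 to 66.3 ± 6.94 RPKM), GSDMC3 (5.43 to 16.9) and GSDMC4 (2.81 to 7.56) rose with DZNep. By the test of the difference, their changes were larger than with Tamoxifen by 1.77 (adjusted p = 0.00279), 1.54 (0.00133) and 1.23 (4.59e-04). How reads shared by such close family members were assigned is not given in the sources used here. FOSB went down with DZNep (-1.26) and up with Tamoxifen (1.33), and KRT14 went up with DZNep (0.85) and down with Tamoxifen (-0.49). Those Tamoxifen calls were lost without Tamoxifen 1 (adjusted p = 0.0956 and 0.243) or Tamoxifen 2 (0.230 and 0.339).

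Of interferon ligands and receptors, 0 rose and 1 fell of 7 with DZNep, both over all genes and adjusted over the list alone (mean -0.15, camera adjusted p = 0.118; lower with fry at 0.00134), and 0 of 7 passed limma with Tamoxifen (adjusted p = 0.862). The gene that fell was IFNE, an interferon of epithelia, from 2.12 ± 0.120 to 0.708 ± 0.101 RPKM (-0.87; adjusted p = 2.84e-04). The list's difference between experiments was -0.18 (adjusted p = 0.136; 0.0367 without EtOH 1).

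Short RNA genes varied far more than other genes. Within a group of the chemical experiment a median of 36.4% of them differed by over 2-fold between a pair of libraries, against 38.8% between groups. In the genetic experiment these were 41.9% and 42.6%. For other genes the medians were 0.0544% within and 0.934% between groups with DZNep, and 0.0771% and 0.367% with Tamoxifen.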
